A study of Rattus with 26 samples.

How the data were processed

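RNA from the right hippocampus of 26 male F344 rats was measured, with 1 Affymetrix rat Clariom S array per animal. The animals were 2 or 18 months old at the start and 5 or 21 months old at the end of 3 months of daily dosing through the nose with insulin aspart, a fast-acting insulin analog, or with saline. All animals were tested in a water maze in the last week of dosing, so every hippocampus came from an animal that had swum. The hippocampus was taken whole, and no cell type was sorted.

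Per the submitters' processing notes, array intensities were summarised by the authors with Robust Multiarray Average at the transcript level, which corrects background, quantile-normalises the arrays and fits 1 value per transcript cluster and array on the log2 scale. Partek is named among the authors' tools; its version and that of the RMA implementation are not given in the sources used here. The deposited table holds log2 values between 2.18 and 19.93, not centred per gene. The base of the logarithm is not written in the table. Means above 16 on that scale occurred in 216 transcript clusters, more than a scanner of 16 bits can give as a log2 intensity, so either the scale was stretched or the base is not 2, which the sources used here do not settle. Every log2 change and fold below is on the table's own scale, and a fold can therefore differ from the ratio of RNA amounts. Array medians lay between 6.64 and 6.72, the Pearson correlation across transcript clusters between any 2 arrays between 0.981 and 0.995, and 0 pairs of arrays were identical.

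The table holds 24834 features, of which 1646 are controls and 23188 are transcript clusters. Of these clusters, 15049 carried 1 gene symbol, 0 carried several, and 8139 could not be named from the annotation used here. For the 10 genes with more than 1 cluster, the brightest cluster was kept, which left 15037 genes. A gene was tested if its value lay above the 30th percentile of the table, 5.06, on at least 5 arrays, the size of the smallest group. This left 11475 genes and removed 3562 dim ones.

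Groups came from the sample titles and held 6 young saline, 5 young aspart, 8 aged saline and 7 aged aspart animals. The means of the 4 groups were fitted together with limma 3.58.1 in R 4.3.3, with 22 residual degrees of freedom and an intensity trend in the prior variance. The 7 contrasts were age in saline animals, age in aspart animals, aspart in aged animals, aspart in young animals, the difference between the last 2 (the interaction), and the mean effect of age and of aspart. Tests were two-sided, and p was adjusted by the Benjamini-Hochberg method within a contrast, with 0.05 as the threshold. Errors of a change are standard errors from limma, intervals are at 95 percent, and spreads of a group are standard deviations.

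Gene lists for 35 pathways and cell types were fixed before the data were examined, as were the contrasts, the filter, the rule for named genes and most of the alternatives. The lists covered major histocompatibility complex (MHC) classes I and II, complement, homeostatic microglia, activated and phagolysosomal microglia, interferon response, lymphocytes, astrocytes, reactive astrocytes, myelin, oligodendrocyte precursors, immature neurons, cell division, collagens, meningeal fibroblasts, choroid plexus, endothelium, mural cells and erythrocytes. They also covered dentate granule cells, CA pyramidal cells, interneurons, striatal neurons, thalamic and habenular neurons, presynaptic genes, glutamate receptors with the postsynaptic density, calcium handling, immediate early genes, insulin and IGF signalling, glucose transport with glycolysis, oxidative phosphorylation, cholesterol synthesis, heat shock, glucocorticoid response and the circadian clock. A synonym was used only for a listed name that is not itself a current gene symbol; Nov, Mt1a and Arntl were so read as Ccn3, Mt1 and Bmal1. This rule was tightened after results had been seen, when 3 list members, Itgax, Ms4a1 and Dsp, were found matched to other genes by synonym; the matches were corrected and everything was rerun. Each list was tested with camera at a preset correlation of 0.01 between genes, adjusted over the 35 lists of a contrast, and again with a correlation estimated for each list. Camera compares a list with the other genes tested. Members past the gene-level threshold were counted over all genes tested and adjusted over the list alone.

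Named genes were, for each contrast, the up to 12 largest changes in each direction among genes that passed, or the 5 smallest unadjusted p where fewer than 5 genes passed. Symbols of uncharacterised loci and of olfactory and vomeronasal receptors with the prefixes Olr, Olfr and Vom were excluded. Up to 4 members were named of each list. Insr, Igf1r, Irs1, Irs2, Ide, Slc2a4, Slc2a3, Gfap, Fkbp1b and Cd74 were to be given whatever their result.

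Whether aspart moved genes against or with their change with age was asked with a correlation across genes between both effects. Aged saline animals enter both effects with opposite sign, so the 8 were divided into 2 equal sets, 1 for each effect, in all 70 ways, and the mean correlation was compared with 100 permutations of the treatment labels among the aged animals. The separation of positive from negative control features on each array was summarised as the area under the receiver operating characteristic curve. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

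Alternatives were other filters, all clusters whether named or not, the mean of a gene's clusters, quantile normalization or median centring of the arrays, array weights, the variance prior without trend, with a robust fit or left out, only the groups of the contrast, and an estimated camera correlation. The RNA integrity number and a choroid plexus score were each tried as a covariate, the replicate number as a block, and each animal was left out in turn. After the data were seen, the control separation as a covariate, a fit without 2 animals rich in choroid plexus RNA and a fit without the 4 arrays of highest control separation were added. An estimated camera correlation together with such a correction was added for 4 lists, and so was a simulated reversal of 30 genes. The fits were tested on simulated data, with the spread of the real arrays and known changes put in. Array number limits the precision: with 100 genes changed by 0.5 on the log2 scale in each of 10 simulated draws, 42.7 percent were found for aspart in aged animals and 23.4 percent for aspart in young animals, against 97.4 and 92.5 percent for a change of 1. False calls per draw had a mean of 2.2 and 5 there, 13.4 for age in saline animals and 2.7 for age over both treatments. Maze performance, blood values and receptor binding were not analysed here.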

Results

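Hippocampal RNA was profiled on 26 arrays, 1 per rat, from 6 young saline, 5 young aspart, 8 aged saline and 7 aged aspart animals. The design crosses age with 3 months of insulin aspart given through the nose, and asks what age changes in the hippocampus and whether the hormone changes gene expression in young or aged animals. Array medians lay between 6.64 and 6.72 on the log2 scale. RNA integrity numbers lay between 6.5 and 7.8, with group means of 7.32 in young saline, 7.34 in young aspart, 7.33 in aged saline and 7.29 in aged aspart animals. Array number limits the precision. The median 95 percent interval of a gene's change reached 0.30 to either side for age in saline animals, 0.29 for aspart in aged animals and 0.34 for aspart in young animals.

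In saline animals, the genes that rose with age included Cd74, C3, Mpeg1, Npc2, Ctss and Gfap. Cd74, the invariant chain that carries MHC class II molecules, rose from 5.46 ± 0.89 (SD, n = 6) in young to 7.19 ± 0.29 (SD, n = 8) in aged animals, a change of 1.73 ± 0.27 (SE) on the log2 scale or 3.31-fold. Cd74 lay below the filter value on 4 of 11 young arrays, so its fold rests on values near the background and is less certain than the direction. C3, the central component of complement, rose by 1.36 ± 0.20 (2.56-fold), and Mpeg1, a pore-forming protein of macrophages, by 1.07 ± 0.15 (2.09-fold). The lysosomal genes Npc2, a cholesterol carrier, and Ctss, a cysteine protease, rose by 0.82 ± 0.14 and 0.78 ± 0.14. Each of these 5 genes was higher than the young saline mean in 8 of 8 aged saline animals. Aged animals above every young saline animal were 8 of 8 for C3, Mpeg1, Npc2 and Ctss but 4 of 8 for Cd74. Genes chosen for passing or for a small p will mostly show such counts, here and below, so the counts add no separate support. Gfap, the intermediate filament of astrocytes, rose by 0.69 ± 0.12 (1.61-fold) in 8 of 8 animals. The anion exchanger Slc26a7 fell by 1.00 ± 0.21, the secreted guidance cue Sema3c fell by 0.74 ± 0.17, and the cadherin Cdh7 fell by 0.69 ± 0.14, each in 8 of 8 animals.

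For age in saline animals, limma called 30 of 11475 genes, 27 higher and 3 lower in aged animals. In all, 733 genes had an unadjusted p under 0.05, where 574 would be so by chance. Adjusted p was 0.00049 for Cd74, 0.000229 for C3 and Mpeg1, 0.00276 for Npc2, Ctss and Gfap, 0.0207 for Slc26a7, 0.0378 for Sema3c and 0.014 for Cdh7. Other genes that rose were Qdpr, which regenerates the tetrahydrobiopterin cofactor (0.97 ± 0.14), Hpgds, a prostaglandin D synthase (0.89 ± 0.13), Pbld1 (0.88 ± 0.17), the annexin Anxa3 (0.88 ± 0.18), the inhibitory Fc receptor Fcgr2b (0.86 ± 0.20), the sodium-proton exchanger Slc9a3 (0.78 ± 0.17) and Gipr, the receptor of an incretin hormone (0.75 ± 0.16). The adjusted p of these genes ran from 0.000229 for Qdpr and Hpgds to 0.0472 for Fcgr2b. Genes of the insulin pathway did not pass: Insr stood at 0.06 ± 0.14, Igf1r at 0.36 ± 0.13, Irs1 at -0.08 ± 0.14, Irs2 at -0.19 ± 0.16 and Ide at -0.16 ± 0.14, and neither did Slc2a3 (-0.20 ± 0.12) or Fkbp1b (-0.05 ± 0.17). Without moderation of the variance Anxa3, Pbld1, Fcgr2b, Gipr, Slc9a3, Sema3c and Slc26a7 no longer passed, and without the 2 animals rich in choroid plexus RNA, described with the border tissue markers, Gipr and Slc26a7 did not. Several calls depended on single animals and on other settings. Leaving out 1 animal ended the call of Fcgr2b in 15 of 26 fits (adjusted p at most 0.166), of Slc9a3 in 10 (0.154), of Sema3c in 10 (0.139), of Gipr in 8 (0.112) and of Slc26a7 in 5 (0.0776). It ended that of Anxa3 without young saline animal 1 (0.0649) or 3 (0.0614), of Pbld1 without young saline animal 6 (0.0513) and of Cdh7 without young saline animal 1 (0.0687). Of 17 other settings, Fcgr2b lost the call in 7, Sema3c in 4, Slc9a3 and Slc26a7 in 2 each and Anxa3, Pbld1 and Cdh7 in 1 each, and Gipr did in 3 of 16. Simulated draws with 200 changed genes held a mean of 13.4 false calls in this comparison, with 101 in 1 of 10 draws and at most 9 in the other 9. The count was 15 without moderation of the variance, and 15 without young saline animal 1, 2 or 3. It was 16 without aged saline animal 7, 19 without young saline animal 6, 46 with array weights and 48 with control separation as a covariate.

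**Figure D1:**
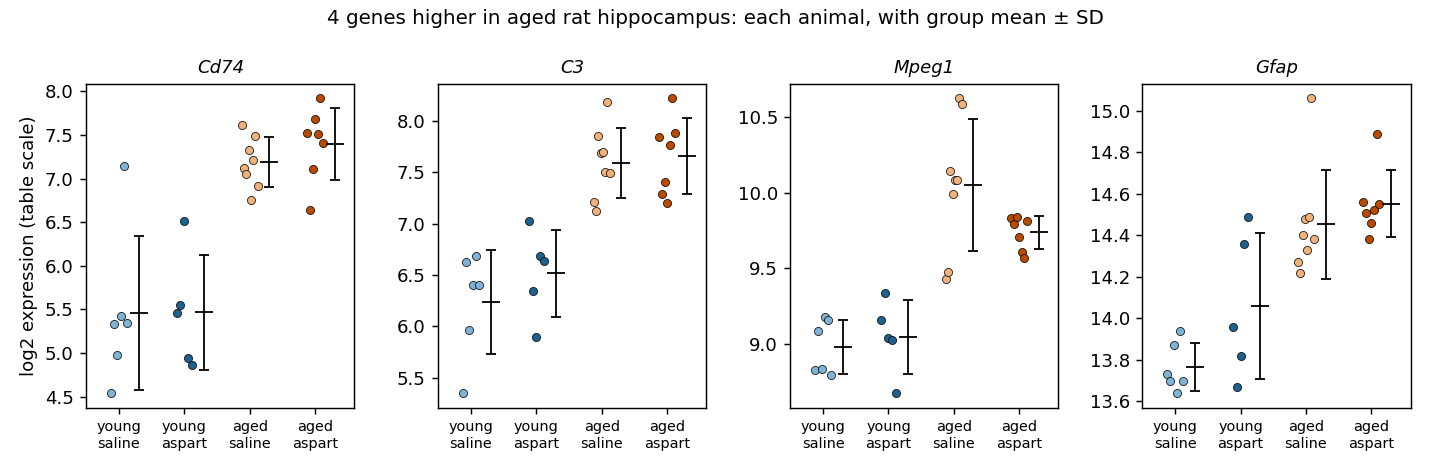
Log2 value of Cd74, C3, Mpeg1 and Gfap (y axis) in each animal, by group (x axis: young saline, young aspart, aged saline, aged aspart); points are animals, and bars give the group mean and SD. Mean Cd74 lay at 5.46 and 5.47 in the young groups and at 7.19 and 7.40 in the aged groups.

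Complement, microglial, MHC class II, reactive astrocyte, interferon and myelin lists lay higher with age in saline animals, although few single members passed. Of 9 complement genes 8 were higher (mean 0.39). C3 passed over all genes, and 3 passed adjusted over the list alone (camera adjusted p = 2.06e-06, adjusted p = 0.0827 with an estimated correlation). Homeostatic microglial genes were higher in 11 of 12 members (mean 0.33). Laptm5, a lysosomal membrane protein, passed at 0.71 ± 0.16, and 3 passed adjusted over the list alone (camera adjusted p = 2.96e-07, adjusted p = 0.095 with an estimated correlation). In the activated and phagolysosomal list 14 of 20 members were higher (mean 0.21). Fcgr2b and Ctss passed, and 5 did adjusted over the list alone (camera adjusted p = 2.93e-05, adjusted p = 0.095 with an estimated correlation). The MHC class II list had a mean of 0.37 but a median of 0.06, with 3 of 6 members higher. Cd74 passed over all genes and 2 members did adjusted over the list alone (camera adjusted p = 0.045, adjusted p = 0.132 with an estimated correlation). This call was lost without any 1 of 11 animals, at most to 0.135, without aged saline animal 7. Reactive astrocyte genes were higher in 11 of 12 members (mean 0.20). Among them 1, Gfap, passed over all genes and adjusted over the list alone (camera adjusted p = 0.000333, adjusted p = 0.0861 with an estimated correlation). Without young saline animal 5 this mean was 0.31. Interferon response genes were higher in 16 of 21 members (mean 0.13), and 0 passed over all genes or adjusted over the list alone. Mx1, an antiviral GTPase, was at 0.47 ± 0.21 (list: camera adjusted p = 0.00658, adjusted p = 0.28 with an estimated correlation). Without aged saline animal 7 the interferon mean was 0.06 and the call was lost (camera adjusted p = 0.226). Myelin genes were higher in 13 of 17 members (mean 0.16). Hapln2, a link protein of the matrix at nodes of Ranvier, passed at 0.68 ± 0.15, over all genes and adjusted over the list alone (camera adjusted p = 0.00127, adjusted p = 0.395 with an estimated correlation). Without aged saline animal 7 the myelin mean was 0.10 and the call was lost (camera adjusted p = 0.0751).

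Immature neuron, immediate early and oxidative phosphorylation lists lay lower with age in saline animals. Immature neuron genes were lower in 11 of 13 members (mean -0.21). Of these 0 passed over all genes and 4 did adjusted over the list alone, with the tubulin Tubb2b at -0.44 ± 0.11 and the transcription factor Sox11 at -0.45 ± 0.16 (camera adjusted p = 0.000581, adjusted p = 0.0827 with an estimated correlation). Immediate early genes, which are induced by neuronal activity, were lower in 15 of 17 members (mean -0.21). Of these 0 passed over all genes or adjusted over the list alone. Nr4a3 stood at -0.35 ± 0.11, Npas4 at -0.48 ± 0.25 and Bdnf, against the rest, at 0.33 ± 0.14 (camera adjusted p = 0.00147, adjusted p = 0.311 with an estimated correlation). Without young saline animal 6 the mean of this list was -0.08 and the call was lost (camera adjusted p = 0.245). Of 46 oxidative phosphorylation genes 43 were lower (mean -0.16), with Ndufb6, a subunit of complex I, at -0.47 ± 0.17 and Cox6b1, a subunit of complex IV, at -0.23 ± 0.09. Of these 0 passed over all genes or adjusted over the list alone (camera adjusted p = 4e-07, adjusted p = 0.28 with an estimated correlation). The oxidative phosphorylation mean of an animal moved with the control separation of its array, pooled over animals after group means were removed (Pearson r = 0.881, permutation p = 2e-05, adjusted p = 2e-05, 26 animals). Spearman rho was 0.787 (permutation p = 8e-05, adjusted p = 8e-05, 2 relations computed), and r was 0.821 without the 2 most distant arrays. By group r was 0.868 in young saline, 0.983 in young aspart and 0.917 in aged aspart animals, but 0.102 in the 8 aged saline animals, whose separation ran only from 0.815 to 0.827. With control separation as a covariate the age difference of this list shrank to -0.091 (camera adjusted p = 0.000414, adjusted p = 0.28 with an estimated correlation). The slope of that covariate rests on the other 3 groups. Insulin and IGF signalling genes stood at a mean of 0.00, with 17 of 30 members higher (camera adjusted p = 0.565), and 0 passed.

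Markers of tissue that borders the hippocampus were also lower in aged saline animals, with 0 members passing over all genes. Meningeal fibroblast genes had a mean of -0.64 with 12 of 13 members lower, among them Dcn, a small proteoglycan, at -0.99 ± 0.32 (camera adjusted p = 9.69e-06, adjusted p = 0.307 with an estimated correlation). Choroid plexus genes had a mean of -0.55 with 8 of 8 members lower (camera adjusted p = 0.0127, adjusted p = 0.484 with an estimated correlation). Mural cell genes had a mean of -0.28 with 10 of 10 lower (camera adjusted p = 0.0174, adjusted p = 0.395 with an estimated correlation). In each of these 3 lists 1 member passed adjusted over the list alone. Young saline animal 5 and young aspart animal 3 stood apart: their choroid plexus means were 11.5 and 10.5, against 7.98 ± 1.73 (SD, n = 6) and 8.00 ± 1.47 (SD, n = 5) in their groups, themselves included. Without both animals the choroid plexus list stood at 0.151 (camera adjusted p = 0.453), the mural cell list at -0.097 (0.265) and the meningeal list at -0.21 (0.00412). With an estimated correlation the camera adjusted p of the meningeal list was then 0.093. Without young saline animal 5 alone the camera adjusted p was 0.773, 0.396 and 0.106, so each call was lost, and the mural cell call was lost without aged saline animal 5 as well (0.0519).

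**Figure D2:**
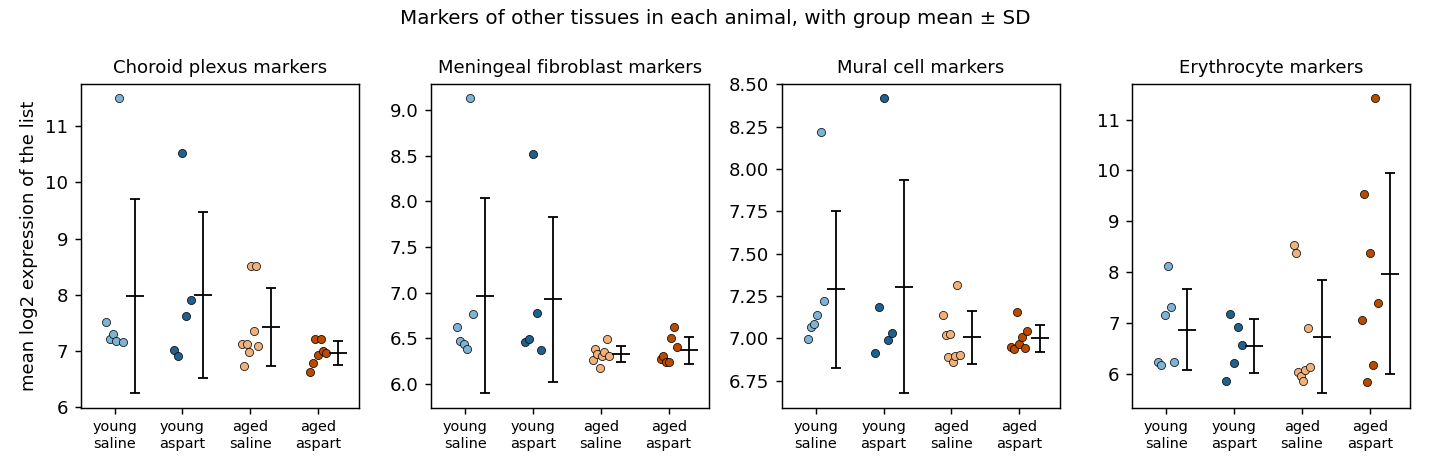
Mean log2 value of the choroid plexus, meningeal fibroblast, mural cell and erythrocyte lists (y axis) in each animal, by group (x axis); points are animals, and bars give the group mean and SD. Young saline animal 5 and young aspart animal 3 reach 11.5 and 10.5 in the choroid plexus list, and the highest aged aspart animal reaches 11.4 in the erythrocyte list.

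For age in saline animals the preset camera test called 13 of 35 lists, 7 higher and 6 lower, and 0 with an estimated correlation. In the preset test 14 lists had an unadjusted p under 0.05. In 50 simulated data sets with no group effect the preset test called a mean of 3.12 lists and at most 9. Regrouping the real animals gave at least 13 lists often enough that chance is not excluded, as given at the end. With quantile normalization of the deposited arrays the MHC class II call was lost (camera adjusted p = 0.0625).

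In aspart animals, age changed 6 genes, all 6 higher in aged animals, with 641 at an unadjusted p under 0.05. Cd74 rose by 1.93 ± 0.29 (3.82-fold, adjusted p = 0.00132), Slc9a3 by 1.21 ± 0.19 (2.32-fold, adjusted p = 0.0015) and C3 by 1.14 ± 0.22 (adjusted p = 0.0221). Mgst1, a microsomal glutathione transferase, rose by 0.97 ± 0.20 (1.97-fold, adjusted p = 0.0467), Tmod1, which caps actin filaments, by 0.77 ± 0.13 (1.71-fold, adjusted p = 0.00736) and Hpgds by 0.69 ± 0.14 (1.61-fold, adjusted p = 0.0407), each in 7 of 7 aged aspart animals. Gfap was at 0.49 ± 0.13 and did not pass (adjusted p = 0.205), and its age effect was not shown to differ between treatments (interaction -0.20 ± 0.18, adjusted p = 1). Of the genes called, 4 were shared between both age comparisons. By chance 0.0157 would be, were genes and comparisons independent. Both comparisons come from 1 fit that shares each gene's variance, so this expected number is likely too low. All 30 of the 30 genes called in saline animals had the same sign in aspart animals. In a fit of these groups alone C3, Hpgds and Tmod1 no longer passed, and without the 2 animals rich in choroid plexus RNA C3, Hpgds and Mgst1 did not. Leaving out 1 animal ended the call of Mgst1 in 19 of 26 fits (adjusted p at most 0.195), of Hpgds in 14 (0.134), of C3 in 6 (0.134) and of Tmod1 without young aspart animal 5 (0.0544). Of 17 other settings, Mgst1 lost the call in 8, Hpgds in 6, C3 in 5 and Tmod1 in 1, and Cd74 and Slc9a3 kept it in every fit. The count of 6 was 2 without young aspart animal 5, 3 without young aspart animal 2 or aged aspart animal 1, 5 or 7, and 3 in a fit of these 2 groups alone. It was 10 with all clusters tested, 10 with array weights, 13 with the RNA integrity number as a covariate and 26 with control separation as a covariate.

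Among the lists in aspart animals, the preset test called 9, and 0 were called with an estimated correlation. Complement (mean 0.32, camera adjusted p = 0.000291, adjusted p = 0.162 with an estimated correlation), homeostatic microglia (0.26, 7.1e-05, adjusted p = 0.272 with an estimated correlation) and activated microglia (0.21, 7.1e-05, adjusted p = 0.162 with an estimated correlation) lay higher. Immature neuron genes lay lower (mean -0.22, camera adjusted p = 0.000128, adjusted p = 0.0718 with an estimated correlation), with the microtubule protein gene Dcx at -0.41 ± 0.17. Oxidative phosphorylation (mean -0.13, 7.1e-05), meningeal (-0.56, 0.000128), choroid plexus (-1.04, 0.00106) and mural cell genes (-0.31, 0.0198) lay lower, each with adjusted p = 0.402 with an estimated correlation. Erythrocyte genes lay higher (mean 1.43, camera adjusted p = 0.000237, adjusted p = 0.162 with an estimated correlation). Without young aspart animal 3 the meningeal mean was -0.16 (camera adjusted p = 0.332), the choroid plexus mean -0.41 (0.332) and the mural cell mean -0.03 (0.819), and these calls were lost. The mural cell call was also lost without young aspart animal 2 (0.051) or aged aspart animal 6 (0.0983). Without aged aspart animal 6 the mean was 0.85 for erythrocytes and 0.17 for homeostatic microglia, and without young aspart animal 4 it was -0.07 for oxidative phosphorylation, with the calls kept.

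Over both treatments, 89 genes changed with age, 70 higher and 19 lower in aged animals, with 1131 at an unadjusted p under 0.05. Cd74 rose 3.56-fold (1.83 ± 0.20, adjusted p = 8.26e-07), C3 2.37-fold (1.25 ± 0.15, adjusted p = 3e-06) and Slc9a3 2.00-fold (1.00 ± 0.13, adjusted p = 1e-05), and Gfap 1.51-fold (0.59 ± 0.09, adjusted p = 0.000153). The folds of Cd74 and Slc9a3 rest on young means close to the filter value. Further genes rose, among them Fcgr2b (0.93 ± 0.15), Mpeg1 (0.88 ± 0.11) and Pld4, a lysosomal exonuclease (0.79 ± 0.13). RT1-Da, an MHC class II chain (0.82 ± 0.17), and Trem2, a microglial lipid receptor (0.49 ± 0.12), also rose. So did Cd4 of the lymphocyte list, which rat macrophages carry as well as T cells (0.83 ± 0.16). Fcrl2 (0.82 ± 0.16), Qdpr (0.85 ± 0.11), Pbld1 (0.82 ± 0.13) and Hpgds (0.79 ± 0.09) rose as well. Gpr17, a receptor of newly formed oligodendrocytes, fell by 0.66 ± 0.11 (adjusted p = 0.000669), Tubb2b fell by 0.44 ± 0.08 (adjusted p = 0.00102), and the fibrillar collagen gene Col1a1 fell by 0.64 ± 0.14 (adjusted p = 0.0149). Slc26a7 fell by 0.89 ± 0.15, Sema3c fell by 0.74 ± 0.12, and Syt10 fell by 0.62 ± 0.12. The transcription factor Snai2 fell by 0.54 ± 0.12, the glycine receptor subunit Glra2 fell by 0.49 ± 0.10 and Fstl5 fell by 0.47 ± 0.10. Smaller falls were in Ccl27 (-0.45 ± 0.10), Ccdc28b (-0.43 ± 0.10) and Emd (-0.42 ± 0.10). Without the 2 animals rich in choroid plexus RNA, Col1a1, Snai2, Ccl27, Ccdc28b and Emd kept their sign and no longer passed, and the same held with a choroid plexus score as a covariate. In all, Col1a1 lost the call in 5 of 15 other settings, Snai2 in 3 of 15, Ccl27 and Ccdc28b in 3 of 16 each and Emd in 2 of 16. Without young aspart animal 3 alone Col1a1 (adjusted p = 0.0522), Snai2 (adjusted p = 0.0544) and Emd (adjusted p = 0.0689) lost it, as did Emd without young aspart animal 5 (adjusted p = 0.0673) and Ccl27 without young aspart animal 4 (adjusted p = 0.0559).

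Over both treatments the preset test called 13 lists, and 2 of these passed with an estimated correlation. They were complement, higher (mean 0.36, camera adjusted p = 7.18e-07, adjusted p = 0.0456 with an estimated correlation), and immature neurons, lower (mean -0.22, camera adjusted p = 8.16e-06, adjusted p = 0.0247 with an estimated correlation). In the complement list 1 member passed over all genes and 5 did adjusted over the list alone. In the immature neuron list the numbers were 1 and 4. This list shares Neurod6 with the CA pyramidal list, so its fall cannot be placed in newly formed neurons alone. Homeostatic microglia (mean 0.29, adjusted p = 0.0887 with an estimated correlation) had 2 members past the threshold over all genes, Laptm5 and the lysophospholipid receptor Gpr34, and 7 adjusted over the list alone. Activated microglia (mean 0.21, adjusted p = 0.0592 with an estimated correlation) had 4, Fcgr2b, Ctss, Ctsz and Trem2, and 9 adjusted over the list alone. MHC class II genes (mean 0.38, median 0.01, 2 of 6 members past the threshold over all genes and adjusted over the list alone; adjusted p = 0.143 with an estimated correlation), reactive astrocytes (mean 0.16, 0.0887), myelin (0.11, 0.474) and erythrocytes (0.64, 0.352) were called higher, each p being the adjusted one with an estimated correlation. Lower, with the same p, were meningeal (mean -0.60, 0.255), choroid plexus (-0.80, 0.289), mural cell (-0.29, 0.289), immediate early (-0.12, 0.446) and oxidative phosphorylation genes (-0.14, 0.209). Of these, 8 of 13 meningeal and 4 of 46 oxidative phosphorylation genes passed adjusted over the list alone, and 0 over all genes. Leaving out 1 animal ended the call of MHC class II for any of 14 animals (camera adjusted p at most 0.147), of erythrocytes for 11 (0.164), of immediate early genes for 7 (0.296, without young saline animal 6), of myelin for 4 (0.11) and of mural cells for young aspart animal 3 (0.0818). The meningeal mean was -0.38 without young saline animal 5, and the choroid plexus mean was -0.44 without it and -0.48 without young aspart animal 3, with the calls kept. The count of genes for age over both treatments was 135 with array weights, 141 with control separation as a covariate and 150 without aged aspart animal 6.

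In aged animals, aspart changed 0 genes by limma. The genes of the hormone's pathway that were to be given in any case had intervals that include 0. Insr, the insulin receptor, stood at 9.30 ± 0.23 (SD, n = 8) in saline and 9.23 ± 0.29 (SD, n = 7) in aspart animals, a difference of -0.07 with a 95 percent interval from -0.35 to 0.21. The receptor Igf1r differed by -0.10 ± 0.12, the adaptors Irs1 and Irs2 by 0.15 ± 0.13 and 0.18 ± 0.15, the insulin-degrading enzyme Ide by -0.05 ± 0.13, the neuronal glucose transporter Slc2a3 by 0.08 ± 0.12 and the calcium release regulator Fkbp1b by 0.01 ± 0.16. Slc2a4, the insulin-regulated glucose transporter, lay above the filter on 0 of 26 arrays (3.50 ± 0.29, SD) and was not tested. Cd74 differed by 0.21 ± 0.26 and Gfap by 0.10 ± 0.12. Of the 27 genes higher with age in saline animals, 11 were lower and 16 higher with aspart in aged animals, and 0 passed. Among them 2 had an unadjusted p under 0.05, both lower, Hpgds (-0.39 ± 0.12, adjusted p = 0.911) and Mpeg1 (-0.31 ± 0.14, adjusted p = 0.911). The 27 genes were chosen for high values in the aged saline animals, which enter both comparisons, and this alone favours lower values with aspart.

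In this comparison 538 genes had an unadjusted p under 0.05, against 574 by chance, and the smallest adjusted p was 0.329, for Loxl3, a lysyl oxidase that cross-links collagen (0.70 ± 0.15, higher in 7 of 7 animals). Loxl3 lay below the filter value on 4 of 8 aged saline arrays and Or6c66b, named next, on 3 of 7 aged aspart arrays, so the size of these differences is uncertain. The next smallest p values belonged to Or6c66b (-0.77 ± 0.18), the transcription factor Gfi1 (-0.77 ± 0.19), Dnaaf10 (-0.51 ± 0.13) and the translation initiation subunit Eif3f (0.45 ± 0.12), with adjusted p = 0.911 each. Counts at the adjusted threshold were 0 with array weights, without moderation and under every other alternative run. Adjusted p of the pathway genes lay between 0.911 for Irs1 and Irs2 and 0.996 for Fkbp1b.

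Of 35 lists, the preset test called 2 for aspart in aged animals, and 0 with an estimated correlation. In 50 simulated data sets with no group effect it called a mean of 3.96, and regrouping the real animals did not exclude chance either. Erythrocyte genes stood higher (mean 1.24, median 0.85, 5 of 5 members; camera adjusted p = 0.00609, adjusted p = 0.938 with an estimated correlation), with the globins Hbb at 2.11 ± 0.85 and Hba-a1 at 2.19 ± 1.10. These means rested on few animals. The list mean of an aged aspart animal ran from 5.84 to 11.4, and 5 of 7 lay above the aged saline mean. Without aged aspart animal 6 the list mean was 0.67 (camera adjusted p = 0.0852) and without animal 2 it was 0.98 (0.0684), so either ended the call. Oxidative phosphorylation genes were higher in 38 of 46 members (mean 0.09, camera adjusted p = 0.0246, adjusted p = 0.978 with an estimated correlation), in 4 of 7 animals, and this list mean moved with the control separation of the arrays as given for age. With that separation as a covariate the mean was -0.017 (camera adjusted p = 0.698), and with quantile normalization the call was lost as well (camera adjusted p = 0.212). It was also lost without any 1 of 6 animals, with a mean of 0.04 (camera adjusted p = 0.503) without aged aspart animal 6. The insulin and IGF list had a mean of 0.05 with 18 of 30 members higher (camera adjusted p = 0.70). Grb14, an inhibitory adaptor of the insulin receptor, stood at -0.24 ± 0.11 and the kinase subunit Pik3r2 at 0.37 ± 0.18. In the heat shock list (mean 0.02, camera adjusted p = 0.921), 1 gene, the co-chaperone Bag3 (0.55 ± 0.16), passed adjusted over the list alone, and 0 over all genes.

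**Figure D3:**
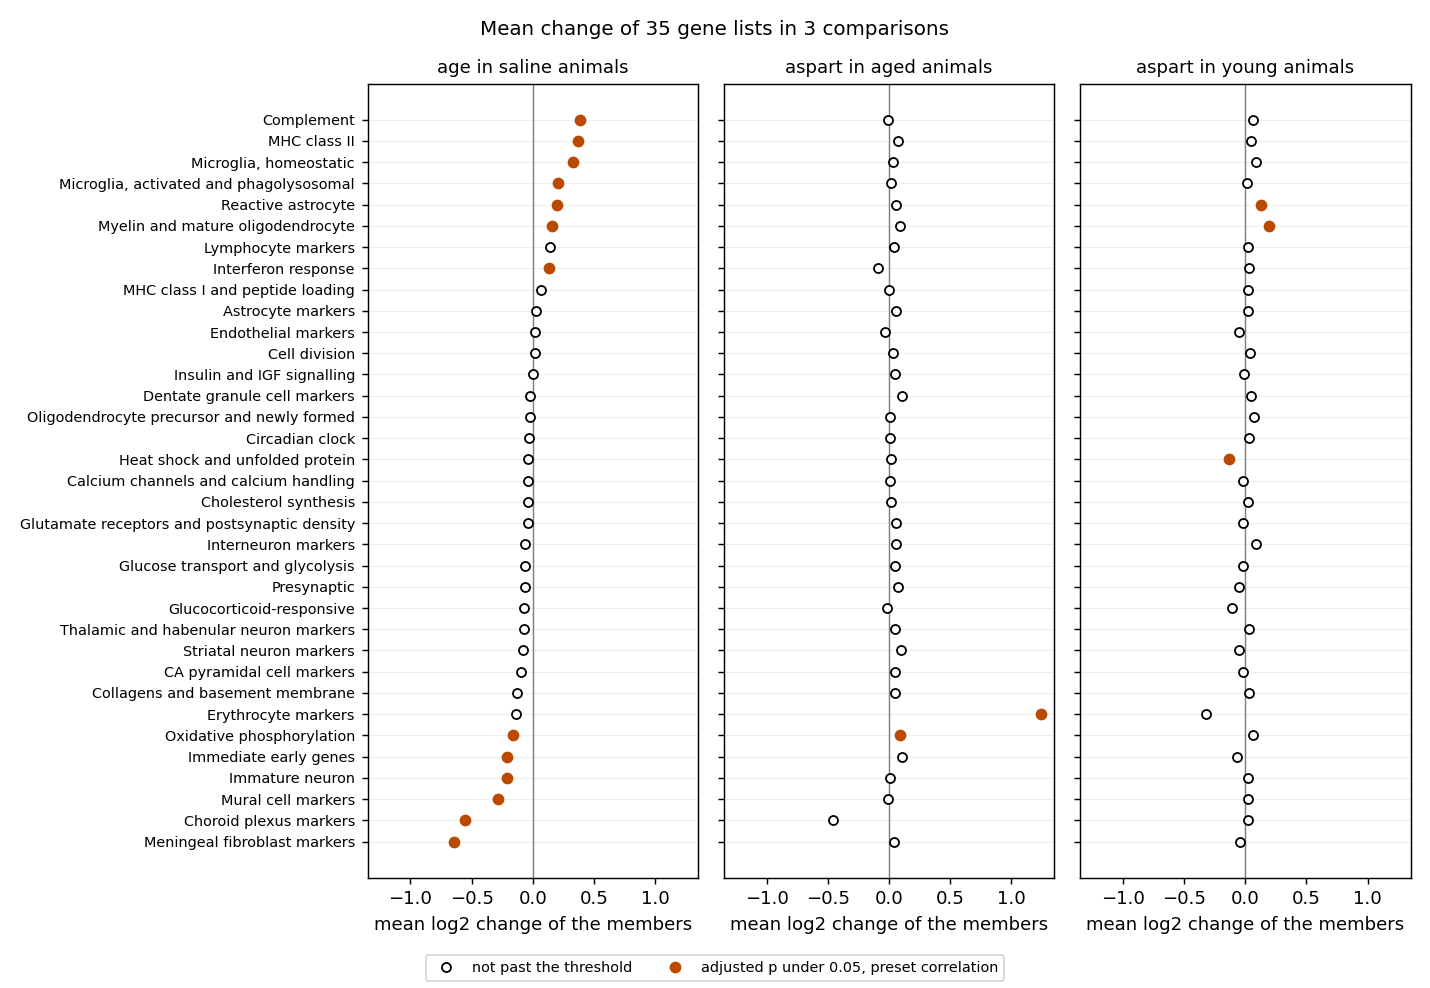
Mean log2 change of the members of each of the 35 gene lists (x axis; lists on the y axis) for age in saline animals, aspart in aged animals and aspart in young animals; a filled point has a camera adjusted p under 0.05 at the preset correlation, an open one has not. Means reach -0.64 for meningeal fibroblasts and -0.55 for choroid plexus with age, and 1.24 for erythrocytes with aspart in aged animals.

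In young animals, aspart also changed 0 genes by limma, with a smallest adjusted p of 0.999. At an unadjusted p under 0.05 were 280 genes, fewer than the 574 that chance gives. The cause of this shortfall was not tested. The count past the adjusted threshold was 0 under every alternative run. Insr differed by 0.03 ± 0.16, Igf1r by 0.16 ± 0.14, Irs1 by -0.07 ± 0.15, Irs2 by -0.13 ± 0.18, Ide by -0.07 ± 0.15, Slc2a3 by 0.02 ± 0.14, Fkbp1b by -0.10 ± 0.19 and Cd74 by 0.01 ± 0.30. Gfap stood at 13.76 ± 0.12 (SD, n = 6) in saline and 14.06 ± 0.35 (SD, n = 5) in aspart animals, a difference of 0.29 ± 0.13 (adjusted p = 0.999). The smallest p values were those of Efcab7 (-0.73 ± 0.19), the sialyltransferase St3gal4 (0.54 ± 0.15), Aif1l (0.64 ± 0.19), the orphan receptor Gpr37 (0.42 ± 0.12) and the phosphatase Dusp16 (0.52 ± 0.16).

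For aspart in young animals the preset test called 3 lists, and 0 with an estimated correlation. Myelin genes were higher in 16 of 17 members (mean 0.19, camera adjusted p = 0.000292, adjusted p = 0.978 with an estimated correlation), with Mog at 0.35 ± 0.15 and Cnp at 0.30 ± 0.14. Reactive astrocyte genes stood at a mean of 0.13 (camera adjusted p = 0.0499, adjusted p = 0.914 with an estimated correlation), with the cytokine receptor Osmr at 0.45 ± 0.17. Heat shock genes stood at -0.13 (camera adjusted p = 0.0435, adjusted p = 0.914 with an estimated correlation), with the chaperone Hspa5 at -0.29 ± 0.14. Single members did not pass. All 3 calls depended on single animals. Myelin lost it without young aspart animal 4 (mean 0.12, camera adjusted p = 0.0656) or 5 (0.12, 0.0717) or young saline animal 6 (0.15, 0.0683). Reactive astrocytes lost it for any of 16 animals, with a mean of 0.05 (0.269) without young aspart animal 3 and of 0.09 (0.554) without young saline animal 6. Without young saline animal 5 that mean was 0.25, with the call kept. Heat shock lost it for any of 7 animals, with a mean of -0.08 (0.24) without young aspart animal 4. These lists were not shown to differ between ages (interaction of myelin -0.10, camera adjusted p = 0.15; reactive astrocytes -0.07, 0.411; heat shock 0.14, 0.0795). Quantile normalization ended the calls of reactive astrocytes (camera adjusted p = 0.0563) and heat shock (camera adjusted p = 0.0502), and without the 4 arrays of highest control separation 0 lists were called.

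Whether the aspart effect differed by age was tested as the interaction, which limma called in 0 genes, with a smallest adjusted p of 1. At an unadjusted p under 0.05 were 203 genes, again fewer than the 574 that chance gives. The smallest p values belonged to Efcab7 (1.00 ± 0.25), Loxl3 (0.83 ± 0.22), Scarf2 (0.70 ± 0.20), Rpp38 (-0.70 ± 0.20) and Cdh7 (0.67 ± 0.20). Scarf2 lay below the filter value on 8 of 8 aged saline, 5 of 5 young aspart and 4 of 7 aged aspart arrays, and Rpp38 and Scarf2 on 3 of 6 young saline arrays each, so their sizes are uncertain, as is that of Loxl3. Erythrocyte genes were the 1 list called (mean 1.56, camera adjusted p = 0.00315, adjusted p = 0.671 with an estimated correlation), with a mean of 0.99 without aged aspart animal 6. For the mean effect of aspart over both ages, limma called 0 genes, with 595 at an unadjusted p under 0.05 and a smallest adjusted p of 0.861. The smallest p values were those of Fam199x (-0.41 ± 0.10), St3gal4 (0.37 ± 0.10), Wbp1 (0.29 ± 0.08), Anxa8 (0.40 ± 0.11) and Gab2 (0.41 ± 0.12). Myelin (mean 0.14, camera adjusted p = 0.0023) and oxidative phosphorylation genes (mean 0.08, camera adjusted p = 0.007) were the 2 lists called, each with adjusted p = 0.983 with an estimated correlation. Myelin lost the call without young aspart animal 5 (camera adjusted p = 0.054) or young saline animal 6 (0.0741), and oxidative phosphorylation without young aspart animal 4 (0.248) or 5 (0.054) or aged aspart animal 6 (0.101).

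Across genes, the change with age and the change with aspart in aged animals showed no detectable opposition or alignment. With the 8 aged saline animals divided between both effects, the mean correlation over 70 divisions was -0.014 (from -0.128 to 0.097), against a mean of 0.009 over 100 permutations of the treatment labels (from -0.199 to 0.212; permutation p = 0.891). Genes are not independent replicates, so the correlation was judged against the permutations alone. In 10 simulated data sets with 200 genes changed with age and fully reversed by aspart the mean was -0.203, against 0.036 with no change, which only just passes the lowest permutation. With 30 such genes, the number called in the data, the mean was -0.053 (from -0.175 to 0.23), so a reversal of that few genes would not be seen. The undivided correlation, in which aged saline animals enter both effects with opposite sign, was -0.363, against a mean of -0.426 in simulations of unchanged groups (from -0.746 to -0.047; p = 0.644). Restricted to genes called for age within a division, the mean was 0.209 (from -0.134 to 0.465) over the 34 divisions with at least 10 such genes, of which a division had at most 19. Permutations were not run for this value, so it speaks neither for nor against alignment.

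**Figure D4:**
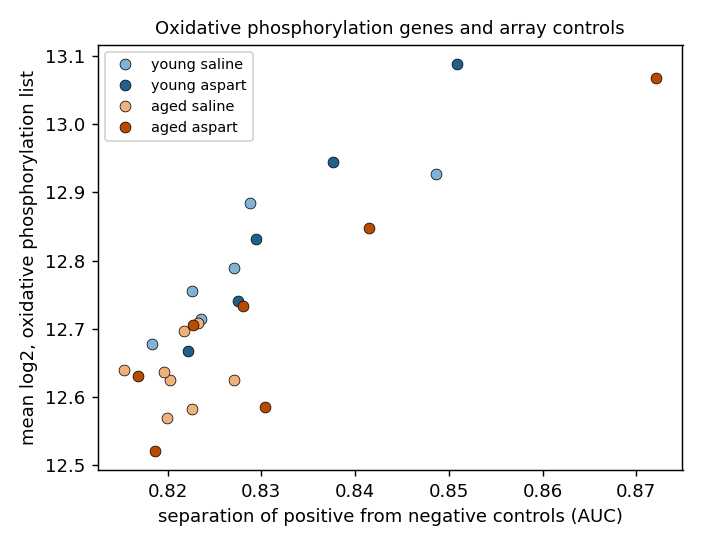
Mean log2 value of the oxidative phosphorylation list (y axis) against the control separation of the array, the area under the curve for positive against negative control features (x axis), for each animal, marked by group. Arrays run from 0.815 to 0.872 in control separation, and list means rise with it in 3 groups but not in aged saline animals (r = 0.102). The pooled r of 0.881 was computed after group means were removed, whereas the points shown are not so adjusted.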

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

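The covariate of control separation, the fit without 2 animals, the means over all members and the estimated correlations after a correction were chosen only after the data were seen, and so were the tests of control separation on microglial genes and of tissue carry-over on the meningeal and choroid plexus lists. Single animals far from the rest of their group were looked for in 116 groups of values, and 15 such values were found, from 5 animals. The groups of values came from lists called in some contrast, a few named genes and array measures. They are neither unselected nor independent, so the 5 percent that chance gives for 1 group is not their chance rate.

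Genes of microglia, complement and MHC class II had a mean change of 0.28 ± 0.06 with age over both treatments over the 47 members tested (median 0.25, 36 higher). Of these 9 passed, Ctss, Ctsz, Laptm5, C3, Trem2, Gpr34, Fcgr2b, Cd74 and RT1-Da, by a mean of 0.865. With the control separation of the arrays as a covariate 9 of these stayed past the threshold (mean 0.894, all members 0.31 ± 0.05). Control separation ran from 0.815 to 0.827 in aged saline and from 0.817 to 0.872 in aged aspart animals. In young animals it ran from 0.818 to 0.849 with saline and from 0.822 to 0.851 with aspart. The ranges overlap and the covariate did not lower the change, so this fit could hardly remove a rise with age. It does not decide about array quality, and the 9 genes were picked for passing. With an erythrocyte score as a covariate 8 stayed (mean 0.85, all members 0.25 ± 0.06), which argues against residual blood as the whole cause. With a choroid plexus score 8 stayed (mean 0.933, all members 0.33 ± 0.06). Choroid plexus genes lay lower in aged animals (mean -0.8), so this last fit could hardly remove a rise with age and does not test carried-over tissue. Age itself, which the design names, stays open, as do differences between the age groups that were not measured. More cells and more RNA per cell cannot be told apart in bulk tissue. Nor can the cell types that carry these genes, which need not be microglia alone.

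Choroid plexus, meningeal and mural cell genes were highest in the same 2 young animals, while aged saline animals 5 and 7 had choroid plexus means of 8.515 and 8.511 (next highest of that group 7.353), which raise the aged mean in the comparison below. Young saline animal 5 had list means of 11.5 for choroid plexus (next highest of its group 7.52), 9.13 for meninges (6.77) and 8.22 for mural cells (7.22); young aspart animal 3 had 10.53 (7.91), 8.52 (6.78) and 8.42 (7.18). Without both, the age difference in saline animals went from -0.553 ± 0.601 to 0.151 ± 0.267 for choroid plexus (camera adjusted p = 0.453). For mural cells it went from -0.283 ± 0.195 to -0.097 ± 0.067 (0.265). The 2 animals were picked for their high means in these lists, so this shows only that both calls rested on them. Tissue carried over at dissection in these animals is a candidate explanation for both lists, which this fit does not test. For meningeal genes the difference went from -0.642 ± 0.349 to -0.21 ± 0.079 and stayed past the threshold at the preset correlation (0.00412) but not with an estimated one (0.307 before, 0.093 after), which argues only weakly against carry-over in these 2 animals as the whole cause, and the call was lost without young saline animal 5 alone (0.106). A loss of border tissue with age stays open and was not tested.

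Oxidative phosphorylation genes moved with control separation in 3 of the 4 groups (Pearson r from 0.868 to 0.983, Spearman rho 0.714 in aged aspart animals). They did not in aged saline animals (r = 0.102), whose separation spans only 0.815 to 0.827. The corrections below thus take their slope from the other groups. Control separation was computed from the same deposited values, so it need not measure array quality alone. Across the 26 arrays the main axis of variation left after group means (20.5 percent of it) correlated with control separation (Pearson r = 0.912, permutation p = 1e-05, the smallest that the permutations can give, adjusted p = 2e-05; Spearman rho = 0.839, permutation p = 2e-05, adjusted p = 4e-05; r = 0.82 without the 2 most distant arrays; 2 relations computed). With control separation as a covariate the higher list mean in aged aspart animals went from 0.092 ± 0.068 to -0.017 ± 0.035 (camera adjusted p = 0.698), so array quality is a candidate explanation for it. The lower list mean in aged saline animals went from -0.156 ± 0.071 to -0.091 ± 0.035 and stayed past the threshold at the preset correlation (0.000414) but not with an estimated one (0.28 before and after), which argues only weakly against array quality as its whole cause. An effect of age on these genes stays open and was not tested further.

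Other single animals stood apart as follows. Young saline animal 6 had a control separation of 0.8486 (next 0.8288). Gfap was 15.06 in aged saline animal 7 (next 14.49) and 14.89 in aged aspart animal 6 (next 14.56). Cd74 was 7.14 in young saline animal 5 (next 5.42), 1 of the 2 animals rich in choroid plexus RNA. Complement genes had a mean of 8.32 in aged aspart animal 6 (next 7.91). Aged saline animal 7 had a mean of 8.74 for homeostatic microglia (next 8.29) and of 7.44 for interferon response (next 6.99). Reactive astrocyte genes had a mean of 7.66 in young saline animal 5 (next 7.10) and of 7.59 in young aspart animal 3 (next 7.19).

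The erythrocyte list was called for the interaction at the preset correlation (difference of 1.56 in the list mean, camera adjusted p = 0.00315) and not with an estimated one (adjusted p = 0.671), so a difference between ages is not established. Aged aspart animals 6 and 2 had Hbb at 14.64 and 10.98, against at most 9.24 in aged saline animals.

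Of the 5639 transcript clusters tested that could not be named here, 11 passed for age in saline animals, 4 for age in aspart animals and 28 for age over both treatments, of which 23 were higher and 5 lower in aged animals; 0 passed in the aspart contrasts and the interaction.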

How the results depend on the processing

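The fits with control separation as a covariate, without the 2 choroid-rich animals and without the 4 arrays of highest control separation were tests chosen only after the data were seen. The counts of genes for aspart in aged animals, in young animals and over both ages and for the interaction were 0 under every alternative run and without each animal. Of 47 named results past the threshold, 30 stayed past it in every setting run. Each result was paired with each setting run for it, fits without an animal included. Of the 1993 such pairs, 1839 kept their side of the threshold, 154 lost it and 0 changed sign. The fits share most of their animals, so the pairs are not independent. Of 45 named results not past the threshold, 0 passed in 1919 such pairs, and 54 pairs changed sign. For each of these the cause was not tested. Signal over background limits dim genes, of which 3562 were left out.

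Genes called for age in saline animals (30) were 46 with array weights, 15 without moderation and 48 with control separation. Without each animal the count ran from 15 to 36, with 15 without young saline animal 1, 2 or 3, 19 without young saline animal 6 and 16 without aged saline animal 7. For age in aspart animals (6) the count was 10 with all clusters and with array weights, 3 in a fit of the groups of the contrast, 13 with the RNA integrity number and 26 with control separation. Without each animal it ran from 2 to 8, with 2 without young aspart animal 5 and 3 without young aspart animal 2 or aged aspart animal 1, 5 or 7. For age over both treatments (89) it was 135 with array weights and 141 with control separation. Without each animal it ran from 82 to 150, the latter without aged aspart animal 6.

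Lists called with an estimated correlation were 0 for age in saline animals (from 13), age in aspart animals (9), each aspart contrast (2, 3 and 2) and the interaction (1), and 2 for age over both treatments (13). For aspart in aged animals the count was 0 with the median filter and 1 with quantile normalization. For aspart in young animals it was 1 with quantile normalization, 1 with control separation and 0 without the 4 arrays. For the interaction it was 3 without a filter, 2 with control separation, 4 without the 2 choroid-rich animals and 2 without the 4 arrays. For aspart over both ages it was 0 without the 4 arrays.

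Without each animal in turn, lists called ran from 10 to 14 for age in saline animals, 8 to 11 for age in aspart animals and 9 to 17 for age over both treatments. For aspart in aged animals they ran from 0 to 3, with 0 without aged aspart animal 2 or 6 and 1 without aged aspart animal 1 or 7 or aged saline animal 2 or 6. For aspart in young animals they ran from 0 to 6, with 0 without young aspart animal 5 or young saline animal 6, 1 without young aspart animal 4 or young saline animal 1 or 4, and 6 without young aspart animal 3 or young saline animal 5. For the interaction they ran from 1 to 6, with 6 without young saline animal 5 or aged aspart animal 5, 5 without young saline animal 2, 4 without young aspart animal 3, young saline animal 4 or aged saline animal 5, and 2 without young aspart animal 1 or 4, aged aspart animal 6 or 7 or aged saline animal 2 or 3. For aspart over both ages they ran from 0 to 4, with 0 without young aspart animal 5, 4 without young saline animal 5 and 1 without young aspart animal 4, young saline animal 6 or aged aspart animal 6.

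Small differences that had not passed changed sign as follows. With array weights, Fkbp1b was 0.024 for age in saline animals and -0.10 for aspart in aged animals, Ide 0.001 for aspart in aged and 0.014 in young animals, and Slc2a3 -0.015 for aspart in young animals. Fkbp1b for aspart in aged animals was -0.011 with quantile normalization and -0.017 with median centring. Cd74 for aspart in young animals was -0.01 with the RNA integrity number. With control separation, Fkbp1b was 0.081 for age in saline animals. For aspart in aged animals Irs2 was then -0.011, Ide 0.051, Slc2a3 -0.015, Gfap -0.002 and Fkbp1b -0.21; for aspart in young animals Insr was -0.001, Slc2a3 -0.02 and Cd74 -0.03. Without the 2 choroid-rich animals, Irs1 was 0.001 for age in saline animals, and for aspart in young animals Insr was -0.014, Irs1 0.09 and Slc2a3 -0.018. Without the 4 arrays, Fkbp1b was 0.007 for age in saline animals, Irs2 -0.047, Ide 0.036 and Fkbp1b -0.173 for aspart in aged animals, and Ide 0.111 and Slc2a3 -0.029 for aspart in young animals.

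Without each animal in turn, Insr for age in saline animals ran from -0.027 to 0.134, Irs1 from -0.144 to 0.001 and Fkbp1b from -0.128 to 0.014. For aspart in aged animals Ide ran from -0.115 to 0.004 and Fkbp1b from -0.115 to 0.078. For aspart in young animals Insr ran from -0.054 to 0.127, Irs1 from -0.147 to 0.008, Ide from -0.177 to 0.1, Slc2a3 from -0.069 to 0.074 and Cd74 from -0.252 to 0.345. The correlation of age and aspart effects (-0.014) was 0.209 over genes called for age, and ran from -0.055 to 0.074 without each aged aspart or young saline animal, with 0.074 without aged aspart animal 6, 0.001 without aged aspart animal 7 and 0.063 without young saline animal 6.

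With the replicate number as a block, 2 lists were called for the interaction (from 1), 23 genes for age in saline animals, 5 for age in aspart animals and 79 for age over both treatments. The sample titles do not say that the numbers pair animals. Residuals of 34 pairs of arrays with the same number in different groups correlated at a mean of 0.07 (from -0.23 to 0.34). Those of 217 other pairs correlated at -0.01, and 8 of 26 animals correlated best with their own number. How many would do so by chance was not computed, so a weak likeness of arrays with the same number is not excluded.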

Other observations

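The genes named in this paragraph were chosen only after their values were seen. Of the 89 genes that changed with age over both treatments, 15 are in a gene list and 74 are in none. The genes that follow are single ones picked from these 74, and no group of them was tested. Fcer1g, a signalling chain of Fc receptors, rose by 0.62 ± 0.10 on the log2 scale (adjusted p = 0.00032) and Fcgr2a by 0.54 ± 0.12 (adjusted p = 0.00815). The cyclooxygenase Ptgs1 (0.63 ± 0.12, adjusted p = 0.00287) and the phospholipase Pla2g7 (0.56 ± 0.09, adjusted p = 0.000454) rose. The engulfment receptors Mertk (0.57 ± 0.12, adjusted p = 0.00769) and Megf10 (0.41 ± 0.10, adjusted p = 0.0345) rose, as did Csf1, a growth factor of microglia (0.47 ± 0.12, adjusted p = 0.041), the fructose transporter Slc2a5 (0.50 ± 0.11, adjusted p = 0.0123) and the small heat shock protein gene Cryab (0.74 ± 0.15, adjusted p = 0.00388). The tubulin Tubb2a fell by 0.35 ± 0.08 (adjusted p = 0.0135) and Stmn2, a microtubule regulator, fell by 0.24 ± 0.06 (adjusted p = 0.0344).

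Gene lists not described above had camera adjusted p values of at least 0.119 for age in saline animals. Neuronal and synaptic lists stood near 0. Dentate granule cells had a mean of -0.02 (median 0.05, camera adjusted p = 0.947), CA pyramidal cells -0.10 (0.141), interneurons -0.06 (0.425). Striatal neurons stood at -0.08 (0.425), thalamic neurons -0.07 (0.574), presynaptic genes -0.06 (0.27), glutamate receptors -0.04 (0.425) and calcium handling -0.04 (0.425). Calb1, a calcium buffer of granule cells, was at -0.46 ± 0.13 (adjusted p = 0.231). It passed adjusted over the list alone in the calcium list and in the dentate granule list. Other cell types were at 0.07 for MHC class I (0.141), 0.14 for lymphocytes (0.213), 0.03 for astrocytes (0.391, with Gfap past the threshold) and -0.02 for oligodendrocyte precursors (0.947). Means were 0.02 for cell division (0.649), -0.13 for collagens (0.228), 0.02 for endothelium (0.425) and -0.14 for erythrocytes (0.917). Metabolic and stress lists were at -0.06 for glycolysis (0.119), -0.04 for cholesterol synthesis (0.425), -0.04 for heat shock (0.425), -0.07 for glucocorticoid response (0.649) and -0.03 for the circadian clock (0.688).

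For aspart in aged animals, the lists not called had camera adjusted p values between 0.36 and 0.973. Interferon response genes had a mean of -0.09 (0.36), immediate early genes 0.11 (0.36), choroid plexus genes -0.46 (0.465), myelin genes 0.09 (0.465), glutamate receptors 0.06 (0.465), and glycolysis 0.05 (0.465). Means were 0.03 for homeostatic microglia, 0.02 for activated microglia, 0.07 for MHC class II, -0.01 for complement and 0.01 for calcium handling (0.921 each). The mean and the test differed in sign for oligodendrocyte precursors and the circadian clock (mean 0.01 each, 0.973 each), and the mean and the median for mural cells and the glucocorticoid response.

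Whether chance can be excluded was tested with 100 splits of the animals into groups of the same sizes, the real one included. This test was chosen before its own result was seen, although the gene counts for age in saline animals had been looked at by then. As many genes as for age in saline animals (30, highest other 1) came in the real split alone. The same held for age over both treatments (89, highest other 1), so chance is unlikely for both counts. As many as for age in aspart animals (6) came in 2 splits, and the other gave 15, so chance is not firmly excluded there. The split tests were not adjusted for their number. For aspart in aged animals (0; highest other 3), aspart in young animals (0; 1), the interaction (0; 1) and aspart over both ages (0; 1), the real count is 0, so all 100 splits have as many whatever the data and the splits say nothing about chance. For lists with age over both treatments (13, highest other 12), the real split alone gave as many, by a narrow margin. Chance was not excluded for age in saline animals (13, highest other 19), with 9 splits, or in aspart animals (9, highest other 12), with 6. Nor was it for aspart in aged animals (2; highest other 7), with 57, aspart in young animals (3; highest other 12), with 49, the interaction (1; highest other 12), with 84, or aspart over both ages (2; highest other 14), with 70.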
